A study of Mus musculus with 16 samples.

How the data were processed

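The 16 arrays were analysed from the Feature Extraction tables that the authors deposited for each hybridisation. The processed signal of each spot is an intensity, background subtracted and spatially detrended but not normalized between arrays, per the file headers (Agilent Feature Extraction 11.5.1.1, 1-colour Cy3 protocol, array design annotated on the mm9 build). The median spot signal and the median local background are raw intensity, also per the file headers. The deposited series values are log2, and their identical quantiles in all 16 columns show quantile normalization by the authors; they were used only as an alternative. Each array held 59305 spots after 3671 control spots were left out, for 55681 probes.

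Probes were named through the RefSeq accession in the array annotation, matched to gene symbols in a RefSeq gene table of the assembly GRCm38.p6. A total of 27656 probes had exactly 1 symbol, for 20972 genes, and 28025 probes had none. Because the array annotation and the gene table belong to different builds, no positions are given, and the gene table served only for names and for the order of genes around Ptn.

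The log2 of the processed signal was taken and the log2 of the array's 75th percentile over all non-control spots was subtracted; this quantity is called the log2 level. Spots that Feature Extraction marked as non-uniform or as population outliers were left out, spots of the same probe were averaged, and probes well above background on at least 4 of the 16 arrays were used, 24148 in all. The probe with the highest mean stood for each gene, which left 12777 genes. Per the labels, the 4 hybridisations of a group are 2 biological and 2 technical replicates, but which hybridisations repeat the same sample is not stated. The arrays of each group were therefore averaged to 2 samples in each of the 3 possible pairings (1+2 and 3+4, 1+3 and 2+4, 1+4 and 2+3). Each pairing was fitted with limma 3.58.1 (lmFit and eBayes, 2-sided) over all 4 groups, with the slide as a term for 1+2 and 3+4, the only pairing it does not cancel in. The largest of the 3 p-values of each gene was kept and adjusted by Benjamini-Hochberg over all genes tested, and genes with an adjusted p under 0.05 were called. This is called the planned test. Ptn was also adjusted over the 6 comparisons alone. These choices, the gene lists, the rule for naming genes and the alternatives not said below to have come later were made before the data were examined.

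A total of 31 gene lists with 691 genes, 687 of them matched to a symbol, covered ES cell state, other cell types, responses to transfection and the surroundings of Ptn. Lists with at least 5 genes measured in every averaged sample were tested with camera in limma with a preset correlation of 0.01, the largest p of the 3 pairings being adjusted over the lists. camera used only genes with a value in every averaged sample, so it can rest on fewer genes than the medians printed beside it. The same test with an estimated correlation was run beside each. Members were also tested one by one, adjusted over the list alone.

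Maps of the arrays showed broad dim and bright patches, and a correction was added after the data had been seen. For each array, the difference of each spot from its median over all 16 arrays was taken at 17906 spots with a median log2 level of at least -1. The median of these differences in a window of 21 by 21 spots was the local shift. The first attempt left out spots in patches, and the second subtracted the local shift and left out spots more than 1 log2 unit from the array's median shift. The last added a minimum of 2 arrays left in every group, because the earlier ones called genes that a single array at the edge of a patch decided. The last is called patch correction and left 11181 genes; narrower and wider windows and limits of 0.5 and 1.5 log2 units were also run. Patch-corrected levels were tested in the planned way and also with the 16 arrays unaveraged and the slide as a term. The unaveraged fit counts technical repeats as replicates, so its p-values are too small by an unknown amount.

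In the planned test, Ptn was named in each comparison, with the 10 largest rises and the 10 largest falls among genes past the threshold that had the same sign in all 4 same-numbered array pairs. Where no gene passed, the 3 rises and 3 falls with the smallest p were named. For each list described, up to 4 members with the smallest p were named, and near Ptn the neighbours past the threshold adjusted over their list alone, or the 2 nearest measured. For patch-corrected levels, a second rule, written after the data had been seen, took the 10 largest rises and falls among genes past adjusted p 0.05 in the unaveraged fit, with unadjusted p under 0.05 in all 3 pairings and the same sign in every same-numbered pair measured.

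Where no array of a group had a signal well above background, the fitted difference is no measure of the fold, and a bound was computed instead. It compared the mean of the other group with a background level, the 95th percentile of the spots not well above background on each array, or with the measured level if that was higher. This background level was chosen after the data had been seen, in place of the lowest spot well above background, against which some bounds were larger than the fitted difference. Where only some arrays of a group were well above background the fitted difference was kept, and it rests in part on levels at background. No fold is given for Klra16, Tlr1, Wfdc15a and Speer1, with only 1 array well above background in EGFP or Ptn_Delta. Rises kept although the lower group had only 1 such array include Fhl2 and Dkk1 against EGFP and Nnmt and Pparg against Ptn_Delta. Dkk1 and Il33 against Ptn_DEL are further cases. The fitted differences of these rises are no close measure of the fold.

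Alternatives were the 16 arrays unaveraged, each pairing alone, replicate blocks, no slide term, each slide alone, normexp background subtraction with an offset of 50, quantile and median normalization, the deposited series values, no filter and a filter on all 16 arrays, only the 2 groups compared, eBayes with a trend, a minimum log2 fold change of 1, the other Ptn probe, and each array left out in turn. The normexp alternative had been planned on mean spot signals, which the tables lack, and used median spot signals. Keeping the marked spots and all forms of patch correction were added after the data had been seen.

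The fits were tested on simulated data with the spread and the missing spots of these arrays, in which 67, 67 and 66 genes changed by 1, 2 and 4 log2 units between 2 groups. The planned test recovered 0% at each size, with 0 false calls. The same test on patch-corrected levels recovered 0, 10.4 and 57.6%, with 0 false calls. The unaveraged patch-corrected fit recovered 32.8, 82.1 and 97.0%, with 54 false calls, and 1 false call in a simulated comparison with no change. The patch search was tested on simulated patches, where it found 90.7% of shifted spots and 0.11% of unshifted spots, with a median error of 0.045 log2 units in the shift. These patches were flat discs with every shift beyond the limit of 1 log2 unit, so finding most of them was built in. Shifts on the real arrays reached -5.94 and 4.31. Whether differences between groups are recovered after the correction of patches was not tested.

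The analysis used R 4.3.3, limma 3.58.1, data.table (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.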

Results

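Mouse E14 embryonic stem (ES) cells, grown with serum and LIF, the cytokine that holds them undifferentiated, were transfected with 1 of 4 constructs, and their RNA was measured 48 h later on 16 single-colour Agilent arrays, 4 for each construct. EGFP was a fluorescent protein alone. The other 3 constructs carried a TALE, a designed DNA-binding protein, aimed at the promoter of Ptn, which codes for pleiotrophin, a secreted heparin-binding growth factor. In Ptn_VP64 the TALE was joined to VP64, a synthetic activator made of repeats of a viral VP16 motif, and in Ptn_DEL to DEL, known as an acidic peptide that opens chromatin. The labels do not say what Ptn_Delta carries. Cells had been sorted for eGFP 24 h after transfection. Each group held 2 biological and 2 technical replicates in an unstated order, so the number of arrays limits the precision throughout.

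The 75th percentile of the signal ranged from 209.3 in EGFP replicate 2 to 1253 in Ptn_VP64 replicate 1. Between 27.1 and 43.8% of spots were well above background. On patch-corrected levels the background level was 0.03 in EGFP replicate 2, against -2.73 to -1.99 on the other EGFP arrays. Weak genes are read at background on that array, among them Ptn at -0.31 and Vnn1 at -0.46. Arrays carried dim and bright patches, shown in the maps of local shift, and the share of spots in patches more than 1 log2 unit from an array's median shift ran from 0.64% in EGFP replicate 4 to 35.57% in EGFP replicate 1. Repeated spots of a probe varied by 52.4 to 74.8% on slide 1, which held replicates 1 and 2, and by 6.88 to 39.3% on slide 2. Patch correction, chosen after the data had been seen, raised the median correlation of an array with the others. On slide 1 this correlation was 0.669 to 0.803 before and 0.857 to 0.955 after. On slide 2 it was 0.772 to 0.862 before and 0.929 to 0.958 after. The correction subtracts each array's local difference from the median over all arrays and leaves out spots in strong patches. A higher correlation is therefore built in and does not show that the correction was right. Differences below are log2 with their standard error, and group levels are log2 against the array's 75th percentile with their SD. On simulated data the planned test recovered 0% of genes changed by 4 log2 units, so its counts of 0 do not show that genes stayed the same.

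**Figure D1:**
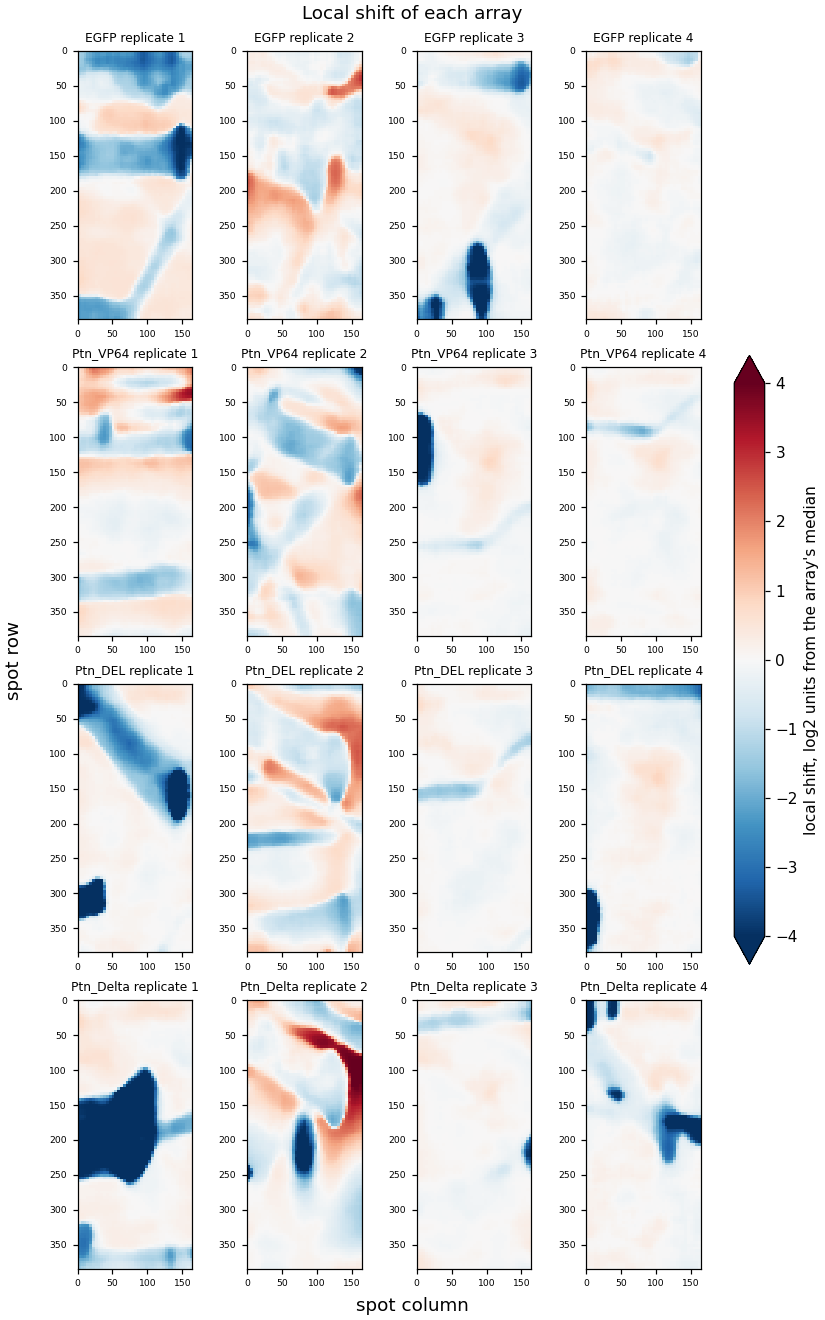
Local shift of the log2 signal over the surface of the 16 arrays, in blocks of 4 by 4 spots, as log2 distance from each array's median shift, drawn from -4 to 4. Each panel is 1 array, its axes are the column and row of spots, and patches cover 0.64 to 35.57% of the spots beyond 1 log2 unit.

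Ptn was the gene that all 3 TALE constructs were aimed at, and its RNA shows whether expression of the target differed. Neither a rise nor a miss tells whether a construct acted at the promoter. For Ptn too, position on the slide cannot be told apart from the construct. Ptn rose after Ptn_VP64, against each of the other 3 groups. In the planned test Ptn was 29.3-fold higher after Ptn_VP64 than after EGFP (4.87 ± 1.04, adjusted p = 0.00772 over the 6 comparisons and 0.677 over all genes). Ptn was also higher after Ptn_VP64 than after Ptn_DEL (4.52 ± 1.04, adjusted p = 0.00772 over the 6 comparisons) and than after Ptn_Delta (3.67 ± 1.04, adjusted p = 0.0159). Neither of these passed over all genes, also not in the unaveraged patch-corrected fit in limma (adjusted p = 0.0645 and 0.0529). Ptn did not pass after Ptn_DEL against EGFP (0.36 ± 0.85, adjusted p = 0.685 over the 6 comparisons), after Ptn_Delta against EGFP (1.21 ± 0.85, adjusted p = 0.289) or after Ptn_DEL against Ptn_Delta (-0.85 ± 0.85, adjusted p = 0.415). The levels of Ptn were -1.21 ± 0.39 after EGFP, -0.85 ± 1.52 after Ptn_DEL and 0.00 ± 0.91 after Ptn_Delta (n = 4 arrays each). Only 1 Ptn_VP64 spot was used, at 3.67, since the other 3 were marked as uneven or as outliers; all 4 spots lay between 2.61 and 3.67, with a mean of 3.10 ± 0.55. With the marked spots kept, the difference of Ptn from EGFP was 4.31 ± 0.79 (adjusted p = 0.00111 over the 6 comparisons), and the other Ptn probe gave 5.08 ± 1.38 (adjusted p = 0.0203). Over the 27 alternatives counted, Ptn was higher after Ptn_VP64 than after EGFP by 3.69 to 5.38. Adjusted over the 6 comparisons alone, it passed in 27 of 27. Over all genes, the test over pairings in limma did not call it with the other probe (adjusted p = 0.944). Nor did it with the marked spots kept (adjusted p = 0.437) or after patch correction (adjusted p = 0.459).

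**Figure D2:**
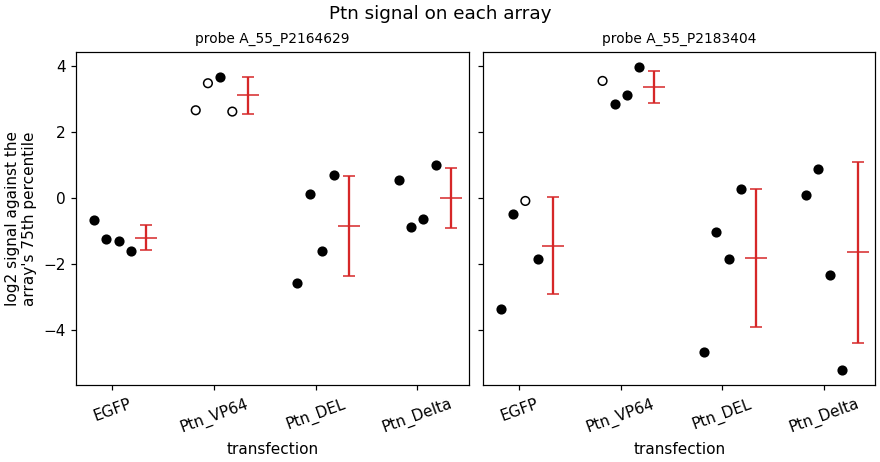
Log2 level of Ptn on each of the 4 arrays of each group, against the array's 75th percentile, with the mean and SD of all 4 arrays in red. The left panel shows the probe of the planned test and the right panel the other Ptn probe. Open points were marked as uneven or as outliers and filled points were not. The 4 Ptn_VP64 arrays sit between 2.61 and 3.67 on the left and between 2.83 and 3.96 on the right.

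The genes next to Ptn were read to see whether expression near the target differed between the constructs. None of those measured was called over all genes in the planned test. Among the 2 nearest, Mtpn, a regulator of actin capping, differed between Ptn_VP64 and EGFP by 0.97 ± 0.75, and Creb3l2, a transcription factor of the secretory pathway, by 1.30 ± 0.60 (adjusted p = 1 over all genes for both). In the unaveraged patch-corrected fit Mtpn changed sign (-0.43 ± 0.33) and Creb3l2 did not (1.09 ± 0.27). On planned levels Mtpn also differed between Ptn_DEL and EGFP, by 1.69 ± 0.85. Adjusted over the list alone, Akr1b3, an aldose reductase, passed in all 3 comparisons with EGFP (Ptn_VP64 4.40 ± 0.86, adjusted p = 0.0321, Ptn_DEL 4.87 ± 0.76, adjusted p = 0.0149, Ptn_Delta 4.88 ± 0.76, adjusted p = 0.0146). These 3 calls of Akr1b3 rested on 1 EGFP array at a level of 1.19. After patch correction Akr1b3 had 3 EGFP arrays with a mean of 5.42 and differences of -0.19, -0.08 and 0.02, so the calls ended. The list of neighbours was not called for Ptn_VP64 against EGFP (adjusted p = 0.983).

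Ptn_VP64 was compared with EGFP to ask what an activator at the Ptn promoter does to expression in the cell. On patch-corrected levels, Il33, a cytokine of the interleukin 1 family, and Nnmt, which methylates nicotinamide, rose in the test over pairings. Nnmt had values on only 2 Ptn_VP64 arrays, which may repeat 1 biological sample. In the unaveraged fit alone, which counts technical repeats as replicates, rises included Fhl2, a LIM domain cofactor of transcription, Dkk1, an inhibitor of Wnt signals, Cyp1b1, a cytochrome P450 oxidase, Thbs1, a matrix glycoprotein, and Vnn1, a pantetheinase. Genes of trophoblast, the outer lineage of the embryo, were called as higher on planned levels with the preset correlation, but not with an estimated one (adjusted p = 0.995) or after patch correction (adjusted p = 0.422, median 2.64). Larger in number than the falls, the rises in the unaveraged fit were 272 of 365 calls.

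In the planned test limma called 0 genes between Ptn_VP64 and EGFP, with 495 at unadjusted p under 0.05 of 12734 tested. The smallest p were of Il33 (6.38 ± 0.60, adjusted p = 0.201), Nnmt (5.13 ± 0.85, adjusted p = 0.55) and Dkk1 (5.13 ± 0.94, adjusted p = 0.55). Among falls not past the threshold, the smallest p were of Haus8, a spindle protein (-6.05 ± 0.78), Rcc2, a chromosome passenger protein (-5.55), and Supt6, a transcription elongation factor (-6.42 ± 0.90), each with 1 Ptn_VP64 array. On patch-corrected levels the same test called 2 genes. Il33 was at least 20-fold higher after Ptn_VP64 (2.57 ± 0.09, n = 3 arrays) than after EGFP, where no array was well above background (adjusted p = 0.00525). Nnmt was at least 7.84-fold higher (1.22 ± 0.13, n = 2 arrays). Only Ptn_VP64 replicates 1 and 4 had a value for Nnmt. In the pairing 1+4 and 2+3 they are repeats of 1 sample, so its call may rest on 1 biological sample. The bound sets the group without signal at its background level. Without Ptn_VP64 replicate 1 or 4 this test called 0 genes (Il33 adjusted p = 0.151 and 0.0921), and without EGFP replicate 1 or 3 or Ptn_VP64 replicate 3 it called 1.

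In the unaveraged patch-corrected fit, 365 genes passed between Ptn_VP64 and EGFP, 272 higher and 93 lower, of which 361 also had p under 0.05 in all 3 pairings. The count fell to 139 without Ptn_VP64 replicate 3 and to 170 without Ptn_VP64 replicate 1, and the fit counts technical repeats as replicates. It is therefore not a number of changed genes. Simulated data gave 54 false calls, a count that depends on the likeness of repeats assumed there. Besides Il33 and Nnmt, rises included Fhl2 (4.94 ± 0.83, adjusted p = 0.015), Dkk1 (4.65 ± 0.85, adjusted p = 0.02), Ptn (4.37 ± 0.84, adjusted p = 0.0298), Cyp1b1 (at least 8.01-fold, adjusted p = 0.00329) and Thbs1 (4.19 ± 0.95, adjusted p = 0.0417). Fhl2, Dkk1 and Ptn each rested on 2 EGFP arrays, and Fhl2 and Dkk1 had only 1 EGFP array well above background. The rule of the same sign rested on 2 array pairs for Fhl2 and 1 for Dkk1. Ptn was read here from its other probe, not that of the planned test. Pmp22, a protein of myelin and epithelial membranes, was 3.95 ± 0.67 higher (adjusted p = 0.0187), Vnn1 at least 2.31-fold, and 3830417A13Rik, of unknown function, 4.15. Falls included 5330411J11Rik (-2.92), an unstudied transcript, Polr3gl, a subunit of RNA polymerase III (-2.65 ± 0.35, adjusted p = 0.0105), the homeobox genes Dmbx1 (-2.59) and Nkx6-3 (-2.42), and Tlr1, a receptor for bacterial lipoproteins, which had a signal well above background on only 1 array of each group. Of these falls, 5330411J11Rik, Polr3gl, Nkx6-3 and Tlr1 rested on 2 EGFP arrays each. The EGFP means of Dmbx1 (-0.77) and Nkx6-3 (-0.44) lay below the background level of EGFP replicate 2 (0.03). Vpreb3, a protein of the B cell receptor precursor, was 2.26 ± 0.28 lower in 4 of 4 array pairs (adjusted p = 0.00118). Other falls included Wfdc15a, a protease inhibitor, and Speer1, of male germ cells, each well above background on only 1 EGFP array and no Ptn_VP64 array.

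**Figure D3:**
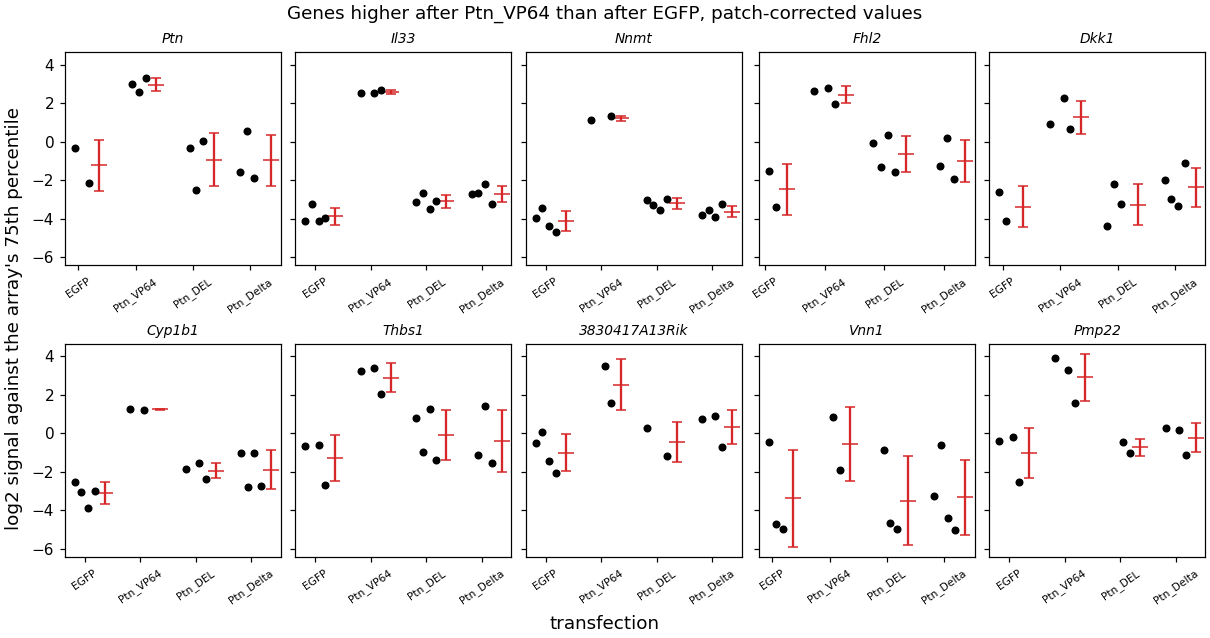
Patch-corrected log2 level of Ptn and 9 other genes named for their rises in Ptn_VP64 against EGFP, on each array of the 4 groups, with mean and SD. Il33 sits at 2.57 ± 0.09 after Ptn_VP64 and at -3.87 ± 0.44 after EGFP. Ptn is shown for its other probe, not that of the planned test.

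Of the 28 gene lists tested between Ptn_VP64 and EGFP, camera called the trophoblast list, with higher levels (12 genes, adjusted p = 4.78e-06, adjusted p = 0.995 with an estimated correlation). Of 15 trophoblast genes tested, 13 were higher, with a median of 1.98. Over all genes 0 of them passed in limma; adjusted over the list alone, 5 rose. These were the transcription factor Gata3 (2.97 ± 0.78, adjusted p = 0.0281), the keratin Krt18 (4.30 ± 1.22, adjusted p = 0.0281) and the placental homeobox gene Rhox6 (3.06 ± 0.74, adjusted p = 0.0281), with the keratin Krt19 (3.86 ± 1.28, adjusted p = 0.0471) and the homeobox gene Esx1 (2.75 ± 0.94, adjusted p = 0.0471). The median of the trophoblast genes was 2.53 on slide 1 and 2.18 on slide 2. After patch correction the trophoblast list was not called (5 genes, adjusted p = 0.422), although 12 genes had a median of 2.64 and Rhox6 passed over all genes in the unaveraged fit (2.86 ± 0.60, adjusted p = 0.0308). The test over pairings, adjusted over the list alone, lost all 5 of these genes there, on 2 or 3 EGFP arrays: Gata3 (2.81 ± 0.71, adjusted p = 0.0518), Rhox6 (2.88 ± 0.74, adjusted p = 0.0518), Krt18 (3.38 ± 1.20, adjusted p = 0.0798), Krt19 (2.94 ± 1.28, adjusted p = 0.0963) and Esx1 (1.26 ± 1.17, adjusted p = 0.437). The other 27 lists were not called, the smallest adjusted p being 0.307, for immediate early genes. None of the list calls in any comparison held with an estimated correlation.

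Ptn_DEL was compared with EGFP to ask how expression differs after a TALE joined to DEL in place of VP64. Chromatin was not measured. Genes of the p53 response, which stops or kills cells with damaged DNA, were called as higher and genes of naive pluripotency as lower on planned levels with the preset correlation, but neither with an estimated one (adjusted p = 0.984 for both). Planned medians against EGFP after Ptn_VP64, Ptn_DEL and Ptn_Delta were 0.34, 0.65 and 0.53 for p53 genes. For naive pluripotency genes they were -0.37, -0.19 and -0.69. All 3 comparisons share the EGFP arrays and went the same way, so these calls do not set Ptn_DEL apart. Ptn itself did not pass.

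Between Ptn_DEL and EGFP limma called 0 genes in the planned test, with 342 at unadjusted p under 0.05 of 12777. The smallest p, none past the threshold, were of Olfr224, an odorant receptor (6.01), Pdpk1, a kinase of insulin signals (5.95), and Sucla2, a citric acid cycle enzyme (5.81), each against 1 EGFP array. The smallest p among lower genes were of Bmper, a regulator of BMP signals (at least 7.94-fold, on 1 EGFP array), Krtap3-1, a hair keratin-associated protein (-3.14), and Rab7b, a GTPase of endosomes (-2.69 ± 0.91). camera called the p53 list with higher levels (20 genes, adjusted p = 0.0177, adjusted p = 0.984 with an estimated correlation), with 25 of 28 genes higher and a median of 0.65 (0.85 on slide 1, 0.71 on slide 2). Its members with the smallest p were Perp, of cell death and adhesion (1.61 ± 0.60), Zmat3, an RNA-binding growth suppressor (2.71 ± 1.02), Cd80, a costimulator of T cells (1.45 ± 0.73), and Gdf15, a stress cytokine (1.23 ± 0.65). The naive pluripotency list was called with lower levels (7 genes, adjusted p = 0.0105, adjusted p = 0.984 with an estimated correlation), with 22 of 33 genes lower and a median of -0.19 (-0.52 on slide 1, -0.04 on slide 2). After patch correction the naive pluripotency list was too small for camera, and 22 of 29 genes were lower with a median of -0.15. The members with the smallest p in the planned test were the corepressor Trim28 (-2.41 ± 1.05), the RNA-binding protein Lin28a (2.58 ± 1.05), the transcription factor Tfcp2l1 (-2.34 ± 1.33) and the Nodal inhibitor Lefty1 (1.30 ± 0.80). None of the members of either list passed (adjusted p = 1 over all genes for each of these 8). The smallest adjusted p of the 26 other lists was 0.0555.

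On patch-corrected levels the planned form of the test called 0 genes between Ptn_DEL and EGFP, with 279 at unadjusted p under 0.05, and the unaveraged fit called 8, all with adjusted p = 0.0495. Higher were Cdh10, a cadherin of neurons (at least 1.01-fold), Itga8, an integrin of kidney development (at least 1.19-fold), Alox5, which starts leukotriene synthesis (at least 1.55-fold), and Adamts1, a matrix protease (at least 1.34-fold). For these 4 no EGFP array was well above background. Lower were Klra16, a receptor of natural killer cells, well above background on only 1 EGFP array, the receptor genes Olfr1496 (-2.70 ± 0.37) and Vmn1r40 (-2.62 ± 0.31), and AW551984, of unknown function (-1.67 ± 0.26). The unaveraged fit called 0 genes without any of the 4 Ptn_DEL arrays, 4 without EGFP replicate 1, 5 without EGFP replicate 2 and 14 without EGFP replicate 4. The p53 list had an adjusted p of 0.0924 here, with 17 of 23 genes higher and a median of 0.27.

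Ptn_Delta was compared with EGFP as the construct whose fused part is not described, to see what a TALE at Ptn does without a named activator. The p53 genes were called as higher after patch correction with the preset correlation, but not with an estimated one (adjusted p = 0.999), and Perp among them did not pass.

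Between Ptn_Delta and EGFP limma called 0 genes in the planned test, with 509 at unadjusted p under 0.05 of 12766. The smallest p, none past the threshold, were of Pdpk1 (5.98), Sucla2 (5.82) and Olfr224 (5.59), each against 1 EGFP array, and among lower genes of Smarcd3, a subunit of chromatin remodelling complexes (-3.13 ± 0.78, adjusted p = 0.981), Galm, a sugar epimerase (-3.40), and Gsg1l, an auxiliary subunit of glutamate receptors, for which no fold could be given because EGFP, the group with the higher level, had no array well above background. camera called 0 of 28 lists, the smallest adjusted p being 0.209, for p53 genes. On patch-corrected levels the p53 list was called with higher levels (10 genes, adjusted p = 0.0162, adjusted p = 0.999 with an estimated correlation), with 20 of 23 genes higher and a median of 0.37 (0.34 on slide 1, 0.47 on slide 2); in the unaveraged fit Perp was 1.34 ± 0.22 higher (adjusted p = 0.111), the kinase Plk2 1.02 ± 0.46 (adjusted p = 0.59), the division inhibitor Cdkn1a 0.68 ± 0.22 (adjusted p = 0.343) and Phlda3, an inhibitor of Akt, 1.15 ± 0.41 (adjusted p = 0.455). The unaveraged fit called 3 genes, each with adjusted p = 0.0141: Itga8 (at least 1.53-fold higher), Cdh10 (at least 1.21-fold higher) and Klra16, which was lower but well above background on only 1 array of each group. The planned form called 0, with 312 at unadjusted p under 0.05. The count of the unaveraged fit was 0 without Ptn_Delta replicate 4, 2 without replicate 1, 8 without replicate 3, 11 without EGFP replicate 4, and 5 without EGFP replicate 1 or 2.

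Ptn_VP64 was compared with Ptn_Delta to set the activator against another TALE at the same promoter. On patch-corrected levels Il33 alone rose in the test over pairings. The unaveraged fit, which counts technical repeats as replicates, also called Nnmt and the nuclear receptor genes Nr2f2 and Pparg as higher. Falls in that fit alone included Egr1, an immediate early transcription factor, Cnr1, the cannabinoid receptor of neurons, and Ptch1, the Hedgehog receptor. Trophoblast genes were called as higher on planned levels with the preset correlation, but not with an estimated one (adjusted p = 0.974) or after patch correction (adjusted p = 0.298), where 12 of 12 were higher with a median of 1.67.

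Between Ptn_VP64 and Ptn_Delta limma called 0 genes in the planned test, with 372 at unadjusted p under 0.05 of 12766; the smallest p were of Il33 (4.86 ± 0.60), Nnmt (4.38 ± 0.85) and Nr2f2 (3.39 ± 0.63), and among lower genes of Haus8, Supt6 and Mapk6, a kinase, each with 1 Ptn_VP64 array. On patch-corrected levels the same test called Il33 alone (adjusted p = 0.0146), and 0 genes without Ptn_VP64 replicate 1, 3 or 4 (Il33 adjusted p = 0.331, 0.0874 and 0.283), and 2 without Ptn_Delta replicate 4. The unaveraged fit called 73 genes, 50 higher and 23 lower. Rises were Il33 (5.31 ± 0.28, adjusted p = 1.31e-06), Nnmt (4.86 ± 0.31, adjusted p = 2.09e-05), Nr2f2 (at least 4.19-fold, adjusted p = 0.00523) and Pparg (2.85 ± 0.39, adjusted p = 0.0063), with Sparcl1, a matrix protein (at least 1.71-fold), Phldb2, of cell adhesion sites (3.33), Cyp1b1 (3.13 ± 0.56), Cfap221, of cilia (at least 3.98-fold), Klra16, well above background on only 1 Ptn_Delta array, and Tspan1, a tetraspanin (at least 3.39-fold). Falls included Megf11, a membrane protein of neurons of the retina (at least 1.30-fold), Actn3, of muscle fibres (-1.86), Cnr1 (-1.85 ± 0.19, adjusted p = 0.00157), Ptch1 (at least 1.14-fold, adjusted p = 0.0383), Ebf1, of B cell and fat cell fate (-1.63), the transporters Abcc4 (-1.61) and Slc5a4b (-1.60), Egr1 (-1.37 ± 0.20, adjusted p = 0.0149) and Irf5, of interferon responses, without a bound because its mean level after Ptn_Delta (-2.39) lay below the mean background level of the Ptn_VP64 arrays. The count was 7 without Ptn_Delta replicate 4, 30 without replicate 2, 35 without replicate 1, and 19 and 23 without Ptn_VP64 replicates 1 and 3. camera called the trophoblast list in the planned levels (12 genes, adjusted p = 5.55e-05, adjusted p = 0.974 with an estimated correlation), with 13 of 15 higher and a median of 1.36 (2.09 on slide 1, 1.28 on slide 2). After patch correction camera had 5 genes of it. In the planned test Gata3 rose by 3.51 ± 0.68 adjusted over the list alone (adjusted p = 0.0205, and 3.10 ± 0.71 with adjusted p = 0.041 after patch correction), and Esx1 was 3.21 ± 0.94 higher without passing.

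Ptn_VP64 was compared with Ptn_DEL to set VP64 against the DEL peptide on a TALE aimed at the same promoter. On patch-corrected levels Il33 alone rose in the test over pairings. The unaveraged fit, which counts technical repeats as replicates, also called Dkk1, Nnmt, Nr2f2, Pparg and Wnt7b, a Wnt ligand of the placenta and the nervous system, as higher. It called Stra8, which starts meiosis and is among the neighbours of Ptn, and Cnr1 as lower. Trophoblast and fibroblast genes were called as higher on planned levels with the preset correlation, but not with an estimated one (adjusted p = 0.992 for both), and trophoblast genes not after patch correction (adjusted p = 0.0867).

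Between Ptn_VP64 and Ptn_DEL limma called 0 genes in the planned test, with 237 at unadjusted p under 0.05 of 12777; the smallest p were of Il33 (5.46 ± 0.60), Dkk1 (4.68 ± 0.94) and Nnmt (4.14 ± 0.85), and among lower genes of Haus8, Supt6 and Ndufa7, of respiratory complex I, each with 1 Ptn_VP64 array. On patch-corrected levels the same test called Il33 alone (adjusted p = 0.01), and 0 genes without Ptn_VP64 replicate 1, 3 or 4 (Il33 adjusted p = 0.249, 0.0929 and 0.188). The unaveraged fit called 94 genes, 63 higher and 31 lower. Rises were Il33 (5.71 ± 0.28, adjusted p = 5.43e-07), Dkk1 (4.56 ± 0.78, adjusted p = 0.0369), Nnmt (4.42 ± 0.31, adjusted p = 5.92e-05), Nr2f2 (at least 3.72-fold, adjusted p = 0.00337), Pparg (at least 3.64-fold, adjusted p = 0.00337) and Wnt7b (3.00 ± 0.55, adjusted p = 0.0382), with Cfap221 (at least 3.53-fold), Phldb2 (3.17), Cyp1b1 (3.15 ± 0.59) and Sparcl1 (at least 1.51-fold). Falls included Stra8 (-3.04 ± 0.47, adjusted p = 0.0387), Trim63, of muscle protein breakdown (-2.10), Cnr1 (-1.98 ± 0.17, adjusted p = 0.000312), Megf11 (at least 1.35-fold), Adgre5, a receptor of leukocytes (-1.81), Actn3 (-1.78), Cidea, of lipid droplets (at least 1.68-fold), and the transporters Slco4a1 (-1.59) and Abcc4 (-1.54). The count was 14 and 17 without Ptn_VP64 replicates 1 and 3, and 16, 36, 54 and 16 without Ptn_DEL replicates 1, 2, 3 and 4. camera called the trophoblast list (12 genes, adjusted p = 3.95e-06, adjusted p = 0.992 with an estimated correlation), with 13 of 15 genes higher, a median of 1.66 (1.61 on slide 1, 1.63 on slide 2) and the smallest p for Esx1 (3.38 ± 0.94) and Gata3 (2.45 ± 0.79), neither past the threshold. It also called the fibroblast list with higher levels (adjusted p = 0.0408, adjusted p = 0.992 with an estimated correlation), with 8 of 12 genes higher and a median of 0.66 (0.31 on slide 1, 1.19 on slide 2), among them the collagens Col1a1 (2.97 ± 1.07) and Col1a2 (1.46 ± 0.90) and the contractile proteins Tagln (2.61 ± 1.73) and Acta2 (2.08 ± 1.52), none past the threshold. After patch correction the trophoblast list was not called on 5 genes, although 12 of 12 were higher with a median of 1.74. The fibroblast list had fewer than 5 genes for camera there, with 10 of 11 higher and a median of 0.70.

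Ptn_DEL was compared with Ptn_Delta to ask whether the chromatin-opening peptide differs from the undescribed part at the same promoter. No gene passed in any of the 4 fits. Between Ptn_DEL and Ptn_Delta limma called 0 genes in the planned test, with 82 at unadjusted p under 0.05 of 12777, and 0 after patch correction, with 11 in the planned form and 79 unaveraged. The smallest p, none past the threshold, were of Capn13, a calpain protease (at least 2.37-fold higher, adjusted p = 1), Ccdc183, a coiled-coil protein (at least 2.13-fold), and Champ1, a kinetochore protein (2.73 ± 0.85), and among lower genes of Casp14, a caspase of the skin (at least 2.84-fold), Clcn7, a lysosomal chloride transporter (-2.64 ± 0.95), and Rell2, a receptor-like protein (-3.58 ± 1.21). Without Ptn_Delta replicate 2 the unaveraged fit called 1 gene, and without replicate 3 it called 2. camera called 0 of 28 lists, the smallest adjusted p being 0.773, shared by 8 lists.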

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

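The tests of the patches and of the position on the slide, and every value on patch-corrected levels, were chosen after the data had been seen; the tests of a different probe, of collagens and of other splits were written before their results were seen. That the splits are read by biological samples was decided afterwards.

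Dim and bright patches covered up to 35.57% of the spots of an array, in EGFP replicate 1. The deviations of spots in neighbouring rows correlated with a median of 0.735 over the arrays (0.319 to 0.912), which describes the patches and does not tell their cause; uneven hybridisation or washing stays open. The construct is argued against, since maps of local shift were no more alike within groups (-0.044) than between them (-0.041), a difference of -0.002.

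Genes were higher after Ptn_VP64 than after EGFP on patch-corrected levels, among them Il33, Nnmt and Fhl2. For 48 of the 272 genes that the unaveraged fit called as higher, a different probe of the same gene passed the filter on signal. That probe was higher too for 43 of the 48 (89.6%), against 51.2% of all genes with another probe. The 95% interval by Clopper-Pearson, 77.3 to 96.5%, treats genes read on the same arrays as independent. For these 48 genes, residue of patches at single spots is argued against as the whole source. The filter left out other probes that stayed at background, so the test does not cover the remaining genes called. The distance between the spots was not tested. RNA from fibroblasts or feeder cells could have added to the rises and stays open. The collagens Col1a1 (3.00 ± 1.00, adjusted p = 0.134), Col1a2 (2.17 ± 1.11, adjusted p = 0.377) and Col3a1 (0.58 ± 0.35, adjusted p = 0.473) are among the most abundant transcripts of fibroblasts. Their median of 2.17 met what was predicted for this explanation, a median of at least 1 log2 unit. The fibroblast list had a median of 0.57 on planned levels (camera, adjusted p = 0.514). On patch-corrected levels its median was 0.43 with 7 of 11 genes higher, it was too small for camera, and 0 of its 11 genes passed. Against Ptn_DEL camera called the list on planned levels (adjusted p = 0.0408, and 0.992 with an estimated correlation). After patch correction 10 of 11 genes were higher against Ptn_DEL and 8 of 11 against Ptn_Delta. The sort for eGFP would remove cells that took up no construct, and the labels mention no feeders. The collagen values are of the unaveraged patch-corrected fit. Position on the slide cannot be told apart from the construct, because every group lay in 1 column of array positions on both slides. An effect of the activator through other genes than Ptn was not tested.

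Each comparison was set against the 35 splits of its 8 arrays into groups of 4, with the 2 groups alone and the arrays unaveraged. Because the arrays repeat 4 biological samples, which make only 3 splits, the splits are too few for a share under 0.05. Ptn_VP64 against EGFP on patch-corrected levels had 22 genes in the real split, 1 split as large, which was the real one, and 1 gene as the highest of the others. On planned levels the same comparison had 1 gene, 2 splits as large and 1 as the highest other, and Ptn_VP64 against Ptn_DEL had 1 gene, 2 splits as large and 161 genes in the split by slide. The other 4 comparisons on planned levels had 0 genes in all 35 splits each. On patch-corrected levels, Ptn_VP64 against Ptn_Delta had 7 genes, 2 splits as large and 14 as the highest other, and Ptn_VP64 against Ptn_DEL had 15 genes, 2 splits as large and 21 in the split by slide. Ptn_DEL against EGFP had 0 genes, with all 35 splits as large and 12 in the split by slide, and Ptn_Delta against EGFP had 0, with 35 and 2, again in the split by slide. Ptn_DEL against Ptn_Delta had 0 genes, with 35 splits as large and 869 in the split of replicates 1 and 3 from replicates 2 and 4, a structure of these arrays apart from the construct. That split follows the row of the slide, with replicates 1 and 3 in row 2 and replicates 2 and 4 in row 1; whether it follows the biological samples too is not known. The unaveraged fits of the report carry the slide as a term but not the row. With the replicate number, which is 1 slide and row, as a block, Ptn_DEL against Ptn_Delta still had 0 genes in limma on patch-corrected levels, with 131 at unadjusted p under 0.05.

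Of 110 groups of 4 values examined, 10 held an array whose gap to the nearest other took a larger part of the range than the 95% critical value of Dixon's test for 4 values, which chance alone passes in about 1 in 20 groups. The 75th percentile of the signal after Ptn_DEL was 648.8 in replicate 4 against 897.6 to 935.3 in the others (0.868 of the range). On patch-corrected levels, after Ptn_Delta, Cidea was at -2.88 in replicate 4 and otherwise at -1.74 to -1.56 (0.864), Nr2f2 at -2.94 in replicate 3 and otherwise at -4.83 to -4.52 (0.836), and Trim63 at -1.35 in replicate 2 and otherwise at 0.13 to 0.25 (0.925). After EGFP, Pparg was at -1.63 in replicate 2 and otherwise at -3.75 to -3.59 (0.925), and Vpreb3 at 0.72 in replicate 2 and otherwise at -0.23 to -0.16 (0.926). The Pparg values lay below the background level of their arrays, which was 0.03 in EGFP replicate 2 and -2.73 to -1.99 in the others. That gap is therefore between readings of background. After Ptn_VP64, Klra16 was at -3.34 in replicate 1 and otherwise at -2.05 to -2.03 (0.985), and Tlr1 at -4.23 in replicate 4 and otherwise at -3.10 to -2.96 (0.89). After Ptn_DEL, Tlr1 was at -4.36 in replicate 3 and otherwise at -3.13 to -2.95 (0.872), and Slc5a4b at -1.91 in replicate 2 and otherwise at -1.33 to -1.25 (0.879).

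Probes without a gene symbol were in no comparison of genes. Of 6588 tested on patch-corrected levels, the unaveraged fit called 15 between Ptn_VP64 and EGFP (9 higher, 6 lower), 3 between Ptn_VP64 and Ptn_Delta (2 higher, 1 lower) and 3 between Ptn_VP64 and Ptn_DEL (2 higher, 1 lower). The test over 3 pairings in limma called 0 of them in each comparison.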

How the results depend on the processing

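Keeping the marked spots and every alternative with patches were chosen after the data had been seen. Values follow the order Ptn_VP64 against EGFP, Ptn_DEL against EGFP, Ptn_Delta against EGFP, Ptn_VP64 against Ptn_Delta, Ptn_DEL against Ptn_Delta and Ptn_VP64 against Ptn_DEL. The planned counts of 0 genes became 5, 0, 0, 4, 0 and 1 with the 16 arrays unaveraged. With pairing 1+3 and 2+4 alone 2 passed in the first comparison, and with 1+4 and 2+3 alone 2 in the first and 1 in the last. The replicate block by number on unaveraged arrays gave 44 (35 higher, 9 lower), 0, 0, 1, 0 and 2 genes, and on patch-corrected levels 663, 17, 11, 240, 0 and 244. Each number is 1 slide and row, so this block also holds those. The numbers do not meet the rule for pairs, since 13 of 24 same-numbered pairs across groups correlated above 0.1 on planned levels and 19 of 24 after patch correction (mean 0.24). As a hint from the data, not the design, 10 and 13 of 16 arrays correlated best with their own number. The replicate block of averaged pairs gave 0 in all 6. Slide 1 alone gave 91 genes (86 lower) for Ptn_Delta against EGFP and 195 (179 higher) for Ptn_DEL against Ptn_Delta, and slide 2 alone gave 1 in the first comparison. Patch spots left out gave 2, 0, 0, 1, 0 and 1, and unaveraged 66, 3, 9, 10, 3 and 5. Patch correction without a minimum of arrays gave 2, 0, 0, 1, 0 and 1, and unaveraged 372, 10, 12, 83, 3 and 92. Patch correction gave 2, 0, 0, 1, 0 and 1, unaveraged 365, 8, 3, 73, 0 and 94. Its pairings alone gave, in the comparisons of Ptn_VP64 with EGFP, Ptn_Delta and Ptn_DEL, 108, 1 and 1 (1+2 and 3+4), 8, 3 and 3 (1+3 and 2+4), and 298, 21 and 29 (1+4 and 2+3). Other windows and limits moved the 365 to between 222 and 471. Ptn stayed higher after Ptn_VP64 than after EGFP, past the threshold adjusted over the 6 comparisons alone, in 27 of 27 alternatives (3.69 to 5.38, adjusted p 0.000318 to 0.0349). Against Ptn_Delta it missed the threshold on slide 2 alone (3.50, adjusted p = 0.0530) and with only the 2 groups (3.50, adjusted p = 0.0839), and against Ptn_DEL with only the 2 groups (4.52, adjusted p = 0.0643), where fewer arrays set the spread. Differences of Ptn that passed in no fit changed sign: Ptn_DEL against EGFP to -0.28 (slide 1), -0.31 (normexp) and -0.10 (patch correction with and without the minimum, and its pairing 1+3 and 2+4), Ptn_Delta against EGFP to -0.11 (other probe), and Ptn_DEL against Ptn_Delta to 0.03 (patch spots left out), 0.42 (patch correction with and without the minimum, and its pairing 1+4 and 2+3), 0.36 (both unaveraged) and 0.41 (its pairing 1+2 and 3+4). After patch correction Ptn was read from its other probe, so the change of probe and the correction cannot be told apart in these differences. Without patch correction the other probe gave 0.06 for Ptn_DEL against EGFP, -0.11 for Ptn_Delta against EGFP and -0.17 for Ptn_DEL against Ptn_Delta. The lists called, planned at 1, 2, 0, 1, 0 and 2, became 0 in all 6 with an estimated correlation, with unaveraged arrays, and with unaveraged patch correction, and 0, 0, 1, 0, 0 and 0 with patch correction. Normexp gave 0 for Ptn_DEL and 1 for Ptn_Delta against EGFP, quantile normalization 1 for Ptn_DEL against EGFP and 1 in the last comparison, and no filter 3 in the first and 2 for Ptn_Delta against EGFP. With each array left out in turn, all planned counts of genes stayed at 0 (limma, 54 to 724 genes at unadjusted p under 0.05), and Ptn ranged over 4.67 to 5.03, -0.08 to 0.60, 0.74 to 1.67, 3.20 to 4.13, -0.99 to -0.03 and 3.64 to 4.66. On planned levels, Ptn after Ptn_VP64 had no value without Ptn_VP64 replicate 3, on slide 1 alone and with the filter on all 16 arrays. On patch-corrected levels, slide 1 had Ptn in replicate 2 alone for these groups, at 2.98 after Ptn_VP64 and -0.31 after EGFP. The range over alternatives does not hold that pair. Except where fewer arrays are named, the cause was not tested. Signal over background limits genes such as Itga8 and Cdh10, whose EGFP arrays were all at background.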

Other observations

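All values on patch-corrected levels below were chosen after the data had been seen, while the gene lists were fixed before.

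Cish, a brake on cytokine signals, was in the list for the LIF and STAT3 signal that holds ES cells undifferentiated. Cish was higher after Ptn_VP64 than after EGFP adjusted over its list alone (2.77 ± 0.55, adjusted p = 0.0211) and in the unaveraged patch-corrected fit (2.73 ± 0.22, adjusted p = 5.06e-05). The list itself was not called on planned levels (camera, adjusted p = 0.983), with 6 of 13 genes higher and a median of -0.38. After patch correction 6 of its 10 genes were higher, with a median of 0.15. In the endoderm list, not called as a list (adjusted p = 0.514), Dkk1 (5.13 ± 0.94, adjusted p = 0.00515), the basement membrane collagen Col4a2 (3.04 ± 0.66, adjusted p = 0.0231) and the endocytic adaptor Dab2 (2.65 ± 0.69, adjusted p = 0.0403) rose adjusted over the list alone. After patch correction the same test kept Cish (2.76 ± 0.23, adjusted p = 0.000535), Dkk1 (4.89 ± 1.03, adjusted p = 0.0171) and Col4a2 (2.12 ± 0.42, adjusted p = 0.0132) but not Dab2, with a smaller difference (1.64 ± 0.56, adjusted p = 0.0904). The unaveraged patch-corrected fit also called Col4a1 (2.15 ± 0.25, adjusted p = 0.000946) as higher and the growth factor gene Fgf17 (-1.29 ± 0.18, adjusted p = 0.00494) as lower. Of the p53 genes, the death receptor Fas (2.05 ± 0.39, adjusted p = 0.0126) and Perp (1.26 ± 0.24, adjusted p = 0.0165) were called as higher. Of the immediate early genes, 2 were called as higher, among them Ier3, a regulator of survival (1.76 ± 0.37, adjusted p = 0.0248), and 1 as lower, Egr1 (-1.04 ± 0.21, adjusted p = 0.0215). Of 29 naive pluripotency genes, 23 were lower with a median of -0.42, and none passed: the nuclear receptor gene Nr0b1 differed by -0.88 ± 0.26 (adjusted p = 0.0855) and Pou5f1, which codes for Oct4, by -1.93 ± 0.79 (adjusted p = 0.266).

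Other list members passed adjusted over their list alone in the planned test. The neural factor Sox1 was lower after Ptn_VP64 than after Ptn_DEL (-3.29 ± 0.81, adjusted p = 0.0384), a call that ended after patch correction with a smaller difference (-2.42 ± 0.75, adjusted p = 0.196). Pcgf6, a Polycomb protein of germ cell gene repression, was lower after Ptn_VP64 than after EGFP (-4.60, adjusted p = 0.0246) and than after Ptn_Delta (-5.34, adjusted p = 0.0282), with too few arrays left to be tested after patch correction. Dkk1 was higher after Ptn_VP64 than after Ptn_Delta (3.83, adjusted p = 0.0409) and than after Ptn_DEL (4.68, adjusted p = 0.0101), and passed in both after patch correction (3.89 ± 0.84, adjusted p = 0.0388, and 5.07 ± 0.84, adjusted p = 0.013). Gm2022, a gene of the state resembling 2-cell embryos, was higher after Ptn_Delta than after EGFP (4.11 ± 0.89, adjusted p = 0.0411), a call that ended after patch correction, where the difference was 1.39 ± 0.54 (adjusted p = 0.439). Near Ptn, Cald1, an actin-binding protein, was higher after Ptn_VP64 than after EGFP in the unaveraged patch-corrected fit (2.65 ± 0.63, adjusted p = 0.0429), and Creb3l2 differed by 1.09 ± 0.27 (adjusted p = 0.0532).

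Without averaging, limma called 5 genes at planned levels between Ptn_VP64 and EGFP: Il33 (6.52 ± 0.51, adjusted p = 1.71e-05), Nnmt (adjusted p = 0.013), Fhl2 (5.23 ± 0.88, adjusted p = 0.0492), Gm9112 (3.88 ± 0.59, adjusted p = 0.0362), of unknown function, and Marveld3, a tight junction protein (3.45 ± 0.54, adjusted p = 0.0362). The last 2 are named after their values were seen.

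Spots for the external spike RNA lay within -0.05 and 0.27 log2 units of the negative controls on all 16 arrays.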
